A study of Arabidopsis thaliana with 9 samples.

How the data were processed

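RNA from Arabidopsis thaliana seedlings was made into libraries with the TruSeq Stranded mRNA kit and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The 9 libraries fall into 3 groups of 3: wild type Columbia (Col), the dana2 mutant and the jmj29 mutant. The titles name the mutant lines dana2-1 and jmj29-1. Here dana2 and jmj29 stand for these lines, and a number after a space (dana2 1) is the library's replicate number, not an allele. All seedlings were 10 days old. Nothing in the labels says that the libraries of a group came from separate plantings, so the p-values measure the spread between these libraries, which may be technical.

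The deposited table holds read counts per gene, 1 column per library, with no normalization. The reads were mapped to TAIR10 with STAR 2.7.6a, and edgeR is also named, per the submitters' processing notes. The counting tool, the annotation release, the strand setting and any filters are not given in the sources used here. Because the strand setting is not known, reads of a gene and of a gene on the opposite strand at the same place cannot be told apart. The table lists 33610 gene identifiers, of which 7147 had no read. In total, 28932 identifiers matched a locus tag of the TAIR10.1 annotation as written and 32843 matched once a suffix was dropped. Symbols and coordinates come from that annotation. The study genes JMJ29, ERF84, ERF15 and GOLS2 were named in the series title or known from the study, and were matched by gene identifier. Members known from the study may rest on these same libraries, so tests over this list are not independent support. Neither the table nor the annotation pairs the name DANA2 with an identifier, so no value is given for that transcript.

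Total counts ran from 17243383 to 38050513 reads per library. Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 20933 genes, and libraries were scaled by TMM. The quasi-likelihood test was fitted to all 9 libraries with genotype as the only term, which left 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. The SE of a log2 change was back-calculated as its absolute value divided by the square root of the quasi-likelihood F statistic, and is approximate. The common biological coefficient of variation was 0.212. Values per library are CPM, the counts scaled by library size after TMM, computed here from the deposited counts, and log2 CPM used a prior count of 2. For genes with almost no reads in a group, the ratio of summed reads over summed totals is given with an exact 95% binomial interval, which covers counting error only.

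In all, 19 gene lists were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 19 lists, and again with an estimated correlation and with fry. The rule named, for each mutant against Col, the 8 genes with the largest increase and the 8 with the largest decrease among called genes with a mean of at least 1 CPM and no overlap between the libraries of the groups. For dana2 against jmj29 it named up to 4 in each direction. It also named the 4 study genes, and up to 4 called members of each list by smallest p. Further gene lists, a correction for transcript length, a fit of code series A alone and lists without JMJ29 were chosen after seeing the data.

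Library codes in the sample descriptions fall into 3 runs of numbers, called code series A, B and C here. What the runs stand for is not stated. Series A holds Col 3, dana2 1 and all jmj29 libraries, series B holds dana2 3, and series C holds Col 1, Col 2 and dana2 2. Differences within a series are differences of mean log2 CPM. No pair of libraries in a group agreed within sampling noise: over genes with at least 20 reads the chi-square per degree of freedom was at least 12.8, so no library was counted as a duplicate.

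The edgeR test was tested on simulated data with 200 changed genes, 100 at each fold size. For dana2 against Col, with 20779 genes tested, 45% of genes changed 2-fold and 89% of genes changed 4-fold were recovered and 13 unchanged genes were called. For jmj29 against Col, with 20767 genes tested, the shares were 41% for 2-fold and 89% for 4-fold changes, with 7 unchanged genes called. For dana2 against jmj29, with 20784 genes tested, they were 55% for 2-fold and 88% for 4-fold changes, with 8 unchanged genes called. These simulated data held no difference between code series and no shift of a whole library. The shares may therefore not hold for the real libraries. Alternatives covered the scaling, the low-count filter, DESeq2 1.42.0, limma-voom, the libraries in the fit, the replicate number and the code series as terms, leaving out each library, organelle genes and the robust option. Similar stretches between transcripts were found with BLAST+ 2.17.0.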

Results

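Transcript levels were measured by RNA sequencing in 10-day-old Arabidopsis seedlings of the wild type Col and of the mutant lines dana2-1 and jmj29-1 (dana2 and jmj29 here), with 3 libraries per genotype. The study concerns the long noncoding RNA DANA2, the transcription factor ERF84 and the response to drought. JMJ29 encodes a histone demethylase of the JmjC family. Total counts were 28214630, 38050513 and 21847738 reads in Col 1 to 3, 19112747, 26709114 and 22760297 in dana2 1 to 3, and 17243383, 22409888 and 26069459 in jmj29 1 to 3. The library dana2 1 stood apart from the other 8 on the first principal component of log2 CPM, with a score of 92.6 against a largest absolute score of 27.6 among the others.

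JMJ29 (AT1G62310, chromosome 1, 23033403 to 23039787, minus strand, TAIR10.1), the gene that names the jmj29 mutant, was lower in every mutant library than in every Col library. Its level was 25.6, 25.7 and 24.1 CPM in Col 1 to 3, 11.3, 10.8 and 10.6 CPM in jmj29 1 to 3, and 6.7, 9.15 and 7.37 CPM in dana2 1 to 3. Reads assigned to JMJ29 were thus present in jmj29, at 10.9 ± 0.374 CPM (SD, n = 3) against 25.1 ± 0.912 CPM (SD, n = 3) in Col. JMJ29 overlaps AT1G08513 on the opposite strand, with 329 bp in common, so its counts may include reads of that gene. ERF84 had 1 read in all 9 libraries together, in Col 3, and was not tested.

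**Figure D1:**
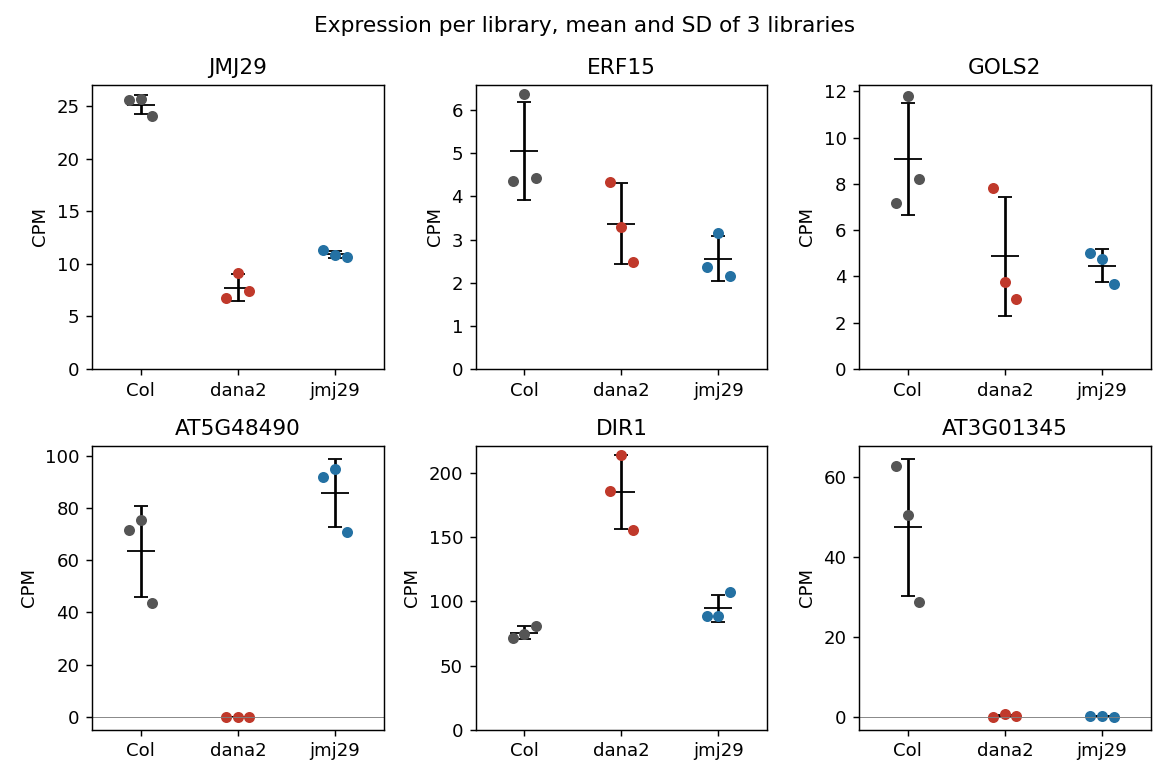
Each panel plots 1 gene, with genotype on the horizontal axis and CPM on the vertical axis, points for libraries, and bar and whiskers for the mean and SD of 3 libraries. JMJ29 was at 25.1 CPM in Col, 7.74 CPM in dana2 and 10.9 CPM in jmj29, and AT5G48490 was near 0 in the dana2 libraries.

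The comparison of dana2 with Col asks which transcripts differ in the mutant of the noncoding RNA. JMJ29 fell by 1.69 on the log2 scale (SE 0.15, edgeR adjusted p = 0.000912), from 25.1 ± 0.912 to 7.74 ± 1.27 CPM (SD, n = 3). The strongest loss among called genes was of AT5G48490, a gene of the lipid-transfer protein family (chromosome 5, 19647784 to 19648362, minus strand), which had 1 read in the dana2 libraries together, in dana2 2, and 5939 in the Col libraries. Their ratio per total read was 0.000216 (95% interval 5.48e-06 to 0.00121). JAZ7, a repressor of jasmonate signalling, rose from 3.15 ± 0.423 to 33.7 ± 11.7 CPM (SD, n = 3; log2 change 3.41, SE 0.54, edgeR adjusted p = 0.0224). ASN1, an asparagine synthetase gene, rose from 39.4 ± 3.82 to 257 ± 28.3 CPM (SD, n = 3; edgeR adjusted p = 0.00786).

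AT1G50040 rose from 3.15 ± 0.768 to 14.7 ± 0.837 CPM (SD, n = 3). The cell wall genes EXLA1 and TCH4 rose from 22 ± 4.07 to 95.2 ± 37.1 CPM and from 371 ± 84 to 1310 ± 520 CPM. AT4G35770, AT2G37030 and PAR1 rose by 2.14, 1.88 and 1.84 on the log2 scale. AT3G01345 had 0, 15 and 3 reads in dana2 1 to 3 and 4420 in Col, a ratio of 0.00523 (95% interval 0.0031 to 0.00828) that was 0.00143 (0.000294 to 0.00418) without dana2 2. GPT2, a plastid sugar phosphate transporter gene, had 1, 4 and 7 reads in dana2 1 to 3 and 414 in Col, a ratio of 0.0372 (95% interval 0.0191 to 0.0658) that was 0.0232 (0.0075 to 0.0546) without dana2 3. The log2 changes of AT1G23110, UGT73C1, ERF13 and AT4G26950 were -2.75, -2.61, -2.01 and -1.49. These genes had edgeR adjusted p-values of at most 0.0396. DIR1 (AT5G48485), which adjoins AT5G48490 and was chosen after its value was seen, rose by 1.29 on the log2 scale (SE 0.16, edgeR adjusted p = 0.00804). DIR1, ASN1, EXLA1 and AT1G23110 each overlap a gene on the opposite strand, so their counts may include its reads. For DIR1 that gene is AT5G48480, which differed by -0.01 on the log2 scale (SE 0.19, edgeR adjusted p = 0.99). This argues against its reads as the source of the DIR1 rise.

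ERF15 differed by -0.60 (SE 0.27) and GOLS2, a galactinol synthase gene, by -0.91 (SE 0.33) on the log2 scale. Neither passed over all genes (edgeR adjusted p = 0.403 and 0.303), and adjusted over the list alone the values were 0.0497 and 0.0277. Within code series A (dana2 1 against Col 3) the differences were -1.83 for JMJ29, -0.03 for ERF15 and -0.07 for GOLS2, and within series C (dana2 2 against Col 1 and Col 2) they were -1.48, -0.67 and -1.27. Without dana2 1, GOLS2 passed with a log2 change of -1.42 (edgeR adjusted p = 0.0463, range over its alternatives 0.0463 to 0.888).

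Of 25 abscisic acid genes, the receptor gene PYL5 and the kinase gene SNRK2.3 rose, by 1.18 (SE 0.20) and 0.92 (SE 0.18) on the log2 scale, and 23 were not called. Adjusted over the list alone 2 were higher and 1 was lower, CYP707A2, a gene of abscisic acid breakdown that was named after its value was seen, at -1.40 (SE 0.29, edgeR adjusted p = 0.0631 over all genes). SNRK2.3 overlaps 2 genes on the opposite strand. Of 22 jasmonate genes, JAZ7 and JAZ6 rose and 20 were not called, and 6 rose adjusted over the list alone. The jasmonate list had a median of 0.40 (camera adjusted p = 0.0076; adjusted p = 0.712 with an estimated correlation). The jasmonate call was lost without Col 1 (camera adjusted p = 0.0533) and without dana2 1 (0.0971), in a range over its alternatives of 0.000447 to 0.712. Of 22 ethylene genes, ERF4 fell from 64.7 ± 3.01 to 30.2 ± 6.32 CPM and ERF5 from 35.1 ± 9.03 to 14.1 ± 1.5 CPM, and the list did not pass (median 0.05 with a camera direction of down, adjusted p = 0.617). Adjusted over the list alone these 2 were lower and 1 was higher, ORA59, also named after its value was seen, at 1.06 (SE 0.28, edgeR adjusted p = 0.152 over all genes). Of 19 salicylic acid genes, WRKY54 fell from 12.2 ± 1.79 to 4.46 ± 0.211 CPM, 3 fell adjusted over the list alone, and the list median was -0.33 (camera adjusted p = 0.00499; adjusted p = 0.712 with an estimated correlation). Without dana2 2 the salicylic acid list did not pass (camera adjusted p = 0.0517, range over its alternatives 0.000447 to 0.712).

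The drought list (26 genes, median 0.11, camera adjusted p = 0.528) had 0 members called by edgeR, 4 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom, and 1 rose adjusted over the list alone. The anthocyanin list (11 genes) had a median of -0.55 and 0 called by edgeR, 5 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom and 4 adjusted over the list alone. The iron list (18 genes) had a median of -0.56 and 0 called by edgeR, 5 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone. Both passed camera (adjusted p = 5.8e-05 and 0.000409; adjusted p = 0.379 for each with an estimated correlation). The study genes passed as a list of 3 that holds JMJ29 (camera adjusted p = 0.000265; adjusted p = 0.167 with an estimated correlation), and with JMJ29 left out the list did not pass (camera adjusted p = 0.057, range over its alternatives 7.53e-06 to 0.306).

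In all, 105 of 20933 genes were called in dana2 by edgeR, 84 higher and 21 lower, 72 of them at least 2-fold. Within code series A and C all 105 differed in the pooled direction, with medians of 1.34 and 0.98 against a pooled 1.1 for the higher genes and of -1.24 and -1.39 against -1.45 for the lower, although they were chosen on the same libraries and series B holds no Col library. With the code series as a term 90 genes were called, of which 52 were among the 105. The term gives dana2 3, alone in series B, no weight in the comparison, so a lost call may reflect fewer libraries. In that fit 10 of the 22 named genes called here did not pass, namely JAZ7, JAZ6, AT4G35770, GPT2, AT1G23110, UGT73C1, ERF13, AT4G26950, ERF4 and WRKY54. With code series A alone, which holds 1 dana2 and 1 Col library, AT4G35770, AT2G37030, TCH4 and PYL5 were at 3.60, 2.66, 2.48 and 1.90 on the log2 scale, and 6 of the 22 did not pass. The count was 17 without Col 1, 4 without Col 2 (1 higher, 3 lower), 12 without Col 3 (5 higher, 7 lower), 45 without dana2 2, 61 without jmj29 1, 36 without jmj29 2 and 100 without dana2 1, and DESeq2 called 537. Of the 22 named genes called here, 15 lost the call without Col 1, 18 without Col 2, 17 without Col 3, 8 without dana2 1, 12 without dana2 2, 2 without dana2 3, 7 without jmj29 1, 11 without jmj29 2 and 4 without jmj29 3, but JMJ29, AT5G48490, AT3G01345 and AT1G50040 kept it each time.

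The comparison of jmj29 with Col asks which transcripts differ in the demethylase mutant. JMJ29 fell by 1.21 on the log2 scale (SE 0.15, edgeR adjusted p = 0.0079), from 25.1 ± 0.912 to 10.9 ± 0.374 CPM (SD, n = 3). JAZ7 rose from 3.15 ± 0.423 to 36.6 ± 31.9 CPM (SD, n = 3; log2 change 3.52, SE 0.54, edgeR adjusted p = 0.016), with 73.1, 22.4 and 14.3 CPM in jmj29 1 to 3 and a log2 change of 2.51 without jmj29 1. EXO, a gene of cell expansion, rose from 538 ± 137 to 1940 ± 366 CPM and its relative PHI-1 from 43.5 ± 20.5 to 159 ± 23.5 CPM (SD, n = 3). AT3G01345 had 3 reads in jmj29 and 4420 in Col, a ratio of 0.00091 (95% interval 0.000188 to 0.00266) that was 0.000411 (1.04e-05 to 0.00229) without jmj29 1 and 0.00151 (0.000311 to 0.00441) without jmj29 3.

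AT1G50040 rose from 3.15 ± 0.768 to 20.2 ± 0.253 CPM (SD, n = 3; edgeR adjusted p = 2e-04). AT4G14548, EXLA1, AT4G16563 and ASN1 rose by 2.28, 2.08, 1.95 and 1.94 on the log2 scale. ERF5, an ethylene response factor gene, went from 35.1 ± 9.03 to 8.12 ± 1.88 CPM (log2 change -2.12, SE 0.23, edgeR adjusted p = 0.00469). The log2 changes of AT5G20790, AT3G47380, AT3G23450, AT4G38860 and GRP-3 were -2.22, -2.07, -1.96, -1.95 and -1.82, and these genes, like DXPS1, had edgeR adjusted p-values of at most 0.0441. These 6 did not pass by edgeR with the code series as a term. Nor did the other named genes called in jmj29, except AT3G01345 and AT1G50040, so 17 of 19 lost the call. Code series A alone leaves Col 3 as the only Col library. With series A alone AT3G47380, AT3G23450 and GRP-3 were at -1.10, -1.14 and -0.57 (edgeR adjusted p = 0.539, 0.172 and 0.525, ranges over their alternatives 3.78e-05 to 0.539, 6.57e-10 to 0.172 and 1.22e-05 to 0.525). GRP-3 was at -1.0 with the code series as a term, and its level was 738, 799 and 247 CPM in Col 1 to 3 and 180, 180 and 144 CPM in jmj29 1 to 3. DXPS1 had 7, 1 and 1 reads in jmj29 1 to 3 and 255 in Col, a ratio of 0.0473 (95% interval 0.0214 to 0.0913). That ratio was 0.0143 (0.00172 to 0.052) without jmj29 1 and 0.0788 (0.0349 to 0.157) without Col 2. Its fitted log2 change was -4.09 (-5.88 to -3.44 over its alternatives), and it did not pass without Col 1, Col 2, dana2 2 or any 1 of the jmj29 libraries (range of edgeR, DESeq2 and limma-voom adjusted p-values over its alternatives 0.000127 to 0.438). DXPS1 overlaps AT3G21490 on the opposite strand, so its counts may include reads of that gene.

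ERF15 differed by -0.98 (SE 0.28) and GOLS2 by -1.03 (SE 0.33) on the log2 scale. Neither passed over all genes (edgeR adjusted p = 0.147 and 0.202), and adjusted over the list alone the values were 0.00644 and 0.01. Without dana2 1, GOLS2 passed with a log2 change of -1.05 (edgeR adjusted p = 0.035, range over its alternatives 0.035 to 0.722). Within code series A (3 jmj29 libraries against Col 3) the differences were -1.14 for JMJ29, -0.79 for ERF15 and -0.88 for GOLS2.

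Of 22 ethylene genes ERF5 and ERF4 fell, 6 adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.000838; adjusted p = 0.359 with an estimated correlation). Of 19 salicylic acid genes WRKY54 fell from 12.2 ± 1.79 to 3.72 ± 1.15 CPM, 1 adjusted over the list alone, with a median of -0.54 (camera adjusted p = 7.91e-05; adjusted p = 0.359 with an estimated correlation). Of 22 jasmonate genes JAZ7 rose, 2 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.026; adjusted p = 0.591 with an estimated correlation). The jasmonate call was lost without Col 1 (camera adjusted p = 0.0793), without jmj29 1 (0.773) and with the code series as a term (0.389), in a range over its alternatives of 0.000193 to 0.773. Without jmj29 3 the ethylene list did not pass (camera adjusted p = 0.067, range over its alternatives 5.4e-05 to 0.359). The study genes passed as a list of 3 (camera adjusted p = 0.000128; adjusted p = 0.141 with an estimated correlation), but 1 of the 3 is JMJ29, the gene that names this mutant. With JMJ29 left out, ERF15 and GOLS2 gave a camera adjusted p = 0.00855 (range over the list's alternatives 3.82e-05 to 0.141), and neither was called alone. Both may have been known from the study of these same libraries, so this is not independent support.

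The trichome, cold, anthocyanin, drought and iron lists (17, 13, 11, 26 and 18 genes) had 0 members called by edgeR or limma-voom, 6, 5, 3, 6 and 3 at an unadjusted p under 0.05, 3, 1, 0, 1 and 2 called by DESeq2, and 4, 2, 0, 0 and 2 adjusted over the list alone. Their medians were -0.53, -0.38, -0.39, -0.21 and -0.15, with camera adjusted p-values of 0.000399, 0.000929, 0.000929, 0.00679 and 0.0417. In the same order they had an adjusted p = 0.33, 0.359, 0.359, 0.588 and 0.476 with an estimated correlation. Camera passed 9 of the 19 lists in jmj29, and 5 to 8 in splits of jmj29 and Col libraries that mixed the genotypes. The drought list did not pass without Col 2 (camera adjusted p = 0.0654) or without jmj29 3 (0.0774), in a range over its alternatives of 3.48e-05 to 0.588. The iron list did not pass without Col 2 (0.0669), Col 3 (0.0893), dana2 1 (0.0528), jmj29 1 (0.374) or jmj29 2 (0.0557), with the code series as a term (0.324) or with RLE size factors in place of TMM (0.0508), in a range of 0.00343 to 0.476.

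In all, 188 of 20933 genes were called in jmj29 by edgeR, 116 higher and 72 lower, and with library size as the only scaling 87 were higher and 94 lower. All 188 differed in the pooled direction within code series A, with medians of 1.06 and -0.95 against a pooled 1.02 and -1.24, although they were chosen on the same libraries. With the code series as a term 2 genes were called, 17 of the 19 named genes called here did not pass, and JMJ29 did not pass (log2 change -1.05, edgeR adjusted p = 0.0822, range over its alternatives 2.01e-10 to 0.165). All jmj29 libraries are in series A, where Col 3 is the only Col library, so lost calls may reflect less information on the difference. The count was 44 without Col 1, 18 without Col 2 (7 higher, 11 lower), 401 without Col 3 (124 higher, 277 lower), 495 without dana2 1, 33 without jmj29 1 (14 higher, 19 lower), 29 without jmj29 2 and 92 without jmj29 3. DESeq2 called 727, 327 higher and 400 lower. Of the 19 named genes called here, 8 lost the call without Col 1, 13 without Col 2, 1 without Col 3, 3 without dana2 2, 9 without jmj29 1, 11 without jmj29 2 and 6 without jmj29 3, but JMJ29, AT3G01345 and AT1G50040 kept it each time.

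The comparison of dana2 with jmj29 asks where the mutants differ from each other. AT5G48490 was the 1 gene called by edgeR, at 0.0119 ± 0.0206 CPM in dana2 and 85.9 ± 13.1 CPM in jmj29 (SD, n = 3; adjusted p = 4.2e-07). JMJ29 differed by -0.49 on the log2 scale (SE 0.15), which did not pass over all genes (edgeR adjusted p = 0.305) and had 0.0232 adjusted over the list alone. With the length correction, chosen after seeing the data, JMJ29 differed by -0.15 (edgeR adjusted p = 0.775). ERF15 and GOLS2 differed by 0.39 (SE 0.28) and 0.12 (SE 0.34), with edgeR adjusted p-values of 0.552 and 0.897.

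The drought, trichome, ethylene, cold and histone and DNA methylation lists (26, 17, 22, 13 and 22 genes) had 0 members called by edgeR or limma-voom, 9, 6, 5, 2 and 4 at an unadjusted p under 0.05, 0, 1, 0, 0 and 0 called by DESeq2, and 0, 4, 2, 1 and 0 adjusted over the list alone. Their medians were 0.36, 0.36, 0.28, 0.30 and -0.14, with camera adjusted p-values of 0.000725, 0.000946, 0.00301, 0.0259 and 0.0261, and each had an adjusted p = 0.688 with an estimated correlation. Of the 19 lists 5 passed camera here, 1 without dana2 1 and 9 without jmj29 1. Without dana2 1 the camera adjusted p was 0.304 for drought, 0.0986 for ethylene, 0.49 for cold and 0.383 for histone and DNA methylation. The ethylene list did not pass without jmj29 3 (0.0895), the cold list without jmj29 2 (0.0958), and the histone and DNA methylation list without dana2 2 (0.141) or jmj29 2 (0.0547). The last list holds JMJ29 and did not pass with it left out (0.057), and the trichome list did not pass with the code series as a term (0.101). The ranges over all alternatives were 3.26e-06 to 0.688 for drought, 7.31e-05 to 0.688 for trichomes, 0.000152 to 0.688 for ethylene, 0.00177 to 0.688 for cold and 0.00187 to 0.795 for histone and DNA methylation. At an unadjusted p under 0.05 edgeR gave 2794 genes here, beside 2591 for dana2 against Col and 2731 for jmj29 against Col. DESeq2 called 181 and limma-voom 2, and edgeR called 2 without Col 2 and 11 without Col 3.

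The genes called in both mutants were compared next. By edgeR 55 were higher in both and 12 lower in both, against 0.47 and 0.07 for independent lists. These lists are not independent, since both comparisons use the same Col libraries and the same fit, which favours calls in the same direction. JAZ7, ASN1, AT1G50040, EXLA1, TCH4, EXO and PHI-1 were higher in both, and JMJ29, AT3G01345, ERF4, ERF5, WRKY54 and AT4G26950 lower in both. In opposite directions there were 0 by edgeR, 0 by DESeq2 and 0 by limma-voom, and 5 at an unadjusted p under 0.05 in both. In 40 simulations every library, Col included, was drawn from the same gene means, and both comparisons shared the simulated Col libraries. At most 1 gene was then called in both. The simulations held no difference between code series and no shift of a whole library, so they cannot show what such differences would give.

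The correlation of log2 fold changes across genes, which are not independent replicates, was 0.494 against a simulated mean of 0.49. It lay within the simulated range of 0.462 to 0.508. The covariance was 0.0943 against a simulated mean of 0.047, a difference of 0.0473. At a like correlation, a larger covariance means a wider spread of log2 fold changes than simulated. The covariance thus cannot tell a shared effect of the mutants from libraries that vary more than simulated. Part of the excess of genes called in both may come from the Col libraries that both comparisons share. The 67 genes became 11 without Col 1, 3 without Col 2, 10 without Col 3, 28 without dana2 2, 15 without jmj29 1 and 14 without jmj29 2. They became 21 with only the 6 libraries compared in each fit, and 2 with the code series as a term.

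**Figure D2:**
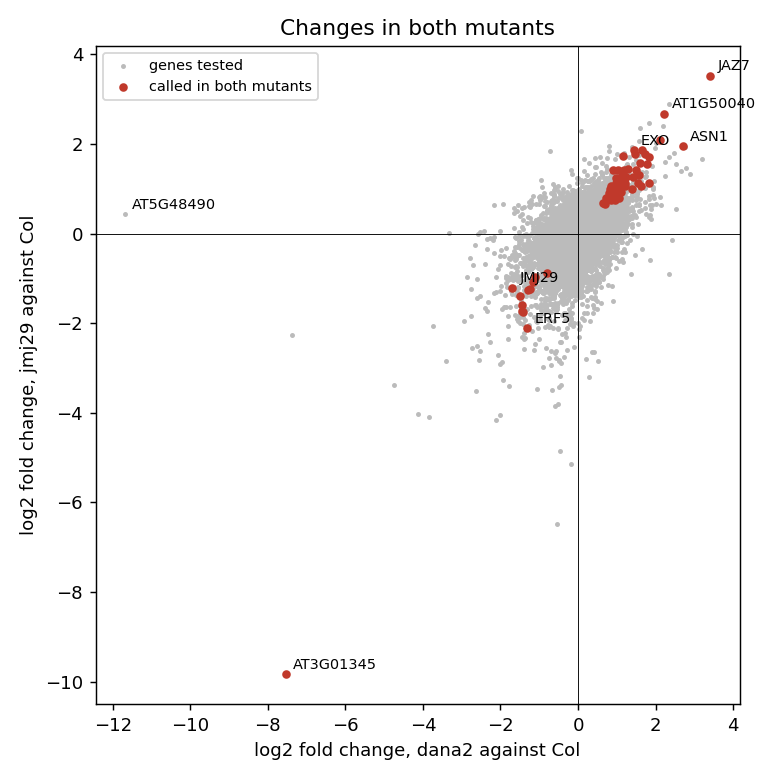
The horizontal axis is the log2 fold change of dana2 against Col and the vertical axis that of jmj29 against Col, with 1 point per gene tested. The 67 genes called in both mutants, in red, lie at the upper right and lower left, and AT5G48490 lies far to the left at -11.68, a fitted value that rests on 1 read.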

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

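The tests of the DIR1 sequence, of the neighbouring genes and of lists without JMJ29 were chosen after the result was seen. AT5G48490 differed between the mutants by the test of that difference (edgeR adjusted p = 4.2e-07). So did 5 gene lists by camera, namely drought (adjusted p = 0.000725), trichomes (0.000946), ethylene (0.00301), cold (0.0259) and histone and DNA methylation (0.0261), each with an adjusted p = 0.688 with an estimated correlation. The last list holds JMJ29 and did not pass with it left out (camera adjusted p = 0.057, range over its alternatives 0.00187 to 0.795). For these lists, 7 of the 10 splits of the 6 libraries gave as many as the real 5, and the highest other gave 10. Most splits that mix the genotypes thus passed as many lists or more, and the others passed 2 or 3. Whether this comes from the libraries or from the preset correlation of the list test was not tested. For genes, 1 of 10 splits gave as many as the real 1, and the highest other gave 0. The splits are too few for a share under 0.05.

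AT5G48490 was nearly without reads in dana2 (1 read against 5939 in Col) while the adjacent DIR1 was higher (185 ± 29.1 CPM against 75.7 ± 4.92 CPM). Assignment of AT5G48490 reads to DIR1 is argued against by their longest identical stretch of 20 bp. Loss of a stretch with neighbouring genes is argued against by the 10 tested neighbours, of which the lowest differed by -0.25 on the log2 scale. What lowered AT5G48490 and raised DIR1 in the dana2 line, whether the mutation or a difference in its background, stays open and was not tested.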

How the results depend on the processing

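The length correction, code series A alone and the lists without JMJ29 were chosen after seeing the data. JMJ29 in dana2 kept its call in all 23 alternatives (-1.85 to -1.61 on the log2 scale), as did AT5G48490, AT3G01345 and AT1G50040 in the comparisons that named them. Over the 40 results of named genes other than the study genes, 700 of 920 values kept the call, 220 kept the direction without it and 0 reversed. These genes were named because they were called, most with no overlap between the libraries of the groups. A reversal was thus unlikely from the start, and its absence is no test of the directions. Over the called lists, 250 of 323 values kept the call, 72 lost it and 1 reversed. The cause was not tested unless given. With no filter on low counts, 185 genes were called in dana2 and 3 between the mutants. DESeq2 called 537 in dana2, 727 in jmj29, 181 between the mutants and 247 in both, and ERF15 passed in jmj29 (-1.01). With limma-voom 2 differed between the mutants and GOLS2 changed sign there (-0.01). With only the 6 libraries compared, 23 were called in dana2, 572 in jmj29 and 21 in both, and GOLS2 passed in jmj29 (-1.06). With the code series as a term, 2 were called in jmj29 and 2 in both, and JMJ29 did not pass in jmj29 (-1.05). Without organelle genes 2 differed between the mutants, as did 2 with the length correction, in which JMJ29 differed between the mutants by -0.15. With code series A alone, 2400 were called in dana2, 2 in jmj29, 3209 between the mutants and 2 in both, JMJ29 did not pass in jmj29 (-1.16) and did between the mutants (-0.69). That fit has 1 Col and 1 dana2 library, assumed to vary like the jmj29 libraries. At a change of at least 2-fold, 116 were called in jmj29 and 39 in both. With a replicate block 104 were called in dana2, 108 in jmj29 and 3 between the mutants. Of 9 same-numbered pairs, 1 had a correlation of deviations over 0.1 (-0.4 to 0.17), and pairs with unlike numbers ran from -0.2 to 0.27. These values gave no sign that the numbers pair the libraries. With 3 libraries a group they cannot exclude it. Leaving out each library gave 4 to 149 genes in dana2, 18 to 495 in jmj29, 1 to 11 between the mutants and 3 to 81 in both. GOLS2 then ran from -1.42 to -0.66 in dana2, from -1.17 to -0.81 in jmj29 and from -0.37 to 0.37 between the mutants, with its sign changed without dana2 1 (-0.37) and without jmj29 3 (-0.01). Lists passing between the mutants ran from 1 to 9. With an estimated correlation 0, 0 and 0 lists passed, with fry 1, 1 and 0, and with code series A alone 3, 5 and 3, in dana2, in jmj29 and between the mutants. With the length correction 8 passed between the mutants, and the histone and DNA methylation list changed direction (adjusted p = 0.795, range over its alternatives 0.00187 to 0.795). No difference of ERF84 could be measured, since it had 1 read in all.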

Other observations

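The gene groups, with their tests, and the tests of transcript length and of clock genes were chosen after the result was seen. Genes of phosphate starvation lay below Col in both mutants. All 18 tested were negative in dana2 (median -0.76), with 0 called by edgeR, 12 at an unadjusted p under 0.05, 5 called by DESeq2 and 0 by limma-voom. In jmj29 17 of 18 were negative (median -1.28) and 4 were called, with log2 changes of -1.68 for SPX1, -1.57 for SRG3, -1.35 for PLDP2 and -1.28 for G3Pp1. With an estimated correlation the group had an adjusted p = 0.0687 in dana2 and 0.0654 in jmj29.

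Of 8 dark-inducible genes, AT4G35770, ASN1 and DIN10 rose in dana2, and ASN1 and DIN10 in jmj29, DIN10 by 1.60 and 1.57 on the log2 scale. Of 7 class II trehalose phosphate synthase genes, TPS8, TPS9 and TPS11 rose in both mutants, by 1.21, 0.85 and 1.15 in dana2 and by 1.07, 0.75 and 1.21 in jmj29. TPS5 lay on the other side, at -0.46 in dana2 (edgeR adjusted p = 0.229) and -0.24 in jmj29 (edgeR adjusted p = 0.531), and adjusted over the list alone 6 were higher and TPS5 was lower in dana2. Of 7 EXORDIUM family genes 3 rose in dana2 and 4 in jmj29. With an estimated correlation each group had an adjusted p = 0.0424 in dana2, and in that order 0.0744, 0.0609 and 0.0609 in jmj29. Of 77 TIR-NBS-LRR disease resistance genes 5 rose in dana2 and 7 in jmj29, among them WRR4 by 1.29 and 1.44 (adjusted p = 0.161 and 0.0744 for the group with an estimated correlation). The adjusted p-values of the 5 groups were adjusted over these 5 alone, and the groups were picked because members were seen to change, so these values carry no weight as tests of the groups.

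The same direction of 67 genes in both mutants was set against 3 explanations. Of 100 regroupings of the 9 libraries, 1, the real one, gave as many, and the highest other gave 43. Besides the real one, those that kept the 3 Col libraries as the reference gave 19, 43 and 19. They are too few to exclude a chance division of the mutant libraries. Regroupings that put Col with mutant libraries gave at most 1, since mixing hides any difference of Col from both mutants. The code series also differ between the genotypes, so the 9 libraries are not exchangeable. A chance assignment of libraries thus cannot be excluded, and an effect of the Col libraries is left. For the shared Col libraries or the code series, comparisons with no library in common (dana2 2 against Col 1 and Col 2, jmj29 against Col 3) had a correlation across genes of 0.314, with single ones from 0.026 to 0.394 and 5 of 6 over 0.1, so this cannot be told apart from an effect of genotype. Time of day at harvest cannot be told apart either, since CCA1, LHY, TOC1 and GI differed by at most 0.24 on the log2 scale but PRR9 by -1.18 in dana2 and -1.08 in jmj29, and the largest absolute difference, 3.86, was of COL1 near the floor. An effect of genotype stays open and was not tested.

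The score of dana2 1 on the first principal component was 92.6, and after removal of each library's trend with transcript length it was 85.4, against at most 28.2 in another library. After removal of the trend with GC content it was 88.1 against 25.3, and with all libraries thinned to 17237777 reads it was 88.9 against 27.6. These values argue against length, GC content or depth, each taken alone, as the whole cause. The library dana2 1 had 21941 genes with a read, the fewest, against 22945 in jmj29 1, which had fewer reads in total. Its deviation from the mean of the other 2 dana2 libraries had a Spearman correlation of -0.36 with transcript length. The Col and jmj29 libraries, taken in the same way, ran from -0.289 to 0.277. The values of dana2 2 (0.13) and dana2 3 (0.344) are set against a mean that includes dana2 1, so they are no independent background. Other technical causes and biological ones were not tested.

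For dana2 against Col, 1 of 10 splits of the 6 libraries gave as many genes as the real 105 and the highest other gave 0, and 2 gave as many lists as the real 5, with 6 in the highest other. For jmj29 against Col, 1 of 10 gave as many genes as the real 188 and the highest other gave 0. For lists, 1 of 10 gave as many as the real 9, and the others gave 5 to 8. Splits of jmj29 and Col that mixed the genotypes thus passed nearly as many lists as the real one. The splits are too few for a share under 0.05.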
